A study of Mus musculus with 135 samples.

How the data were processed

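The series holds RNA sequencing libraries of mouse dorsal dentate gyrus, ventral dentate gyrus and visual cortex, 135 in all, with genotype (wildtype, CREB +/-, CREB -/-) and housing (control, enriched, exercise) given per the labels. Each library has 1 file of counts per gene, deposited as whole numbers with unstranded and strand-specific columns. Per the submitters' processing notes the authors used STAR and Picard with the mouse build mm10, and the versions were not given. The counts of the reverse strand were used, which held between 19.1 and 27.0 times the counts of the other strand. The files list 45318 genes, of which 44585 had a symbol and coordinates in the GENCODE vM21 annotation at hand. Depth was 6.37 to 17.1 M counts in genes per library, with a median of 11.3 M. Reads in no gene, 26.0% to 41.8%, stayed out of library sizes. The sequencing run was read from the file names. No library was left out of the main analysis.

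Within each region all 45 libraries were fitted together in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with a mean for each of the 9 groups of genotype and housing and a term for sequencing run. Genes were filtered with filterByExpr, which left 16691, 17080 and 16849 genes in the dorsal dentate gyrus, ventral dentate gyrus and visual cortex. Library sizes were scaled by TMM, quasi-likelihood tests were used, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. All adjusted p-values of single genes are from edgeR unless another tool is named. Genotype contrasts averaged over the 3 housing groups and housing contrasts over the 3 genotypes. Housing was also compared within each genotype, and the interaction of genotype and housing was tested. Regions were compared in a fit of all 27 groups, with 17955 genes tested and an absolute log2 change of at least 1 required as well. Fitted changes are adjusted for run, so they differ from ratios of the mean CPM.

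Marker and pathway lists, 28 in number with 358 genes, were fixed beforehand, and 4 of these genes were matched by an older symbol. Lists were tested with camera (limma) with a preset correlation between genes of 0.01 and again with an estimated correlation, and members past the threshold were counted over all genes and adjusted over the list alone. Genes were named by a rule: among called genes with a symbol, not sex-linked, not a numbered gene model and with the same sign in every stratum averaged over, those with the smallest p in each direction, up to 10 each, and up to 4 called members of each list. Creb1, Crem and Atf1 were always reported for genotype and Fos, Arc, Bdnf, Dcx and Mki67 for housing. Where the rule gave more genes than the text holds, those with the smallest p were named. Comparisons, tests, lists, the naming rule and the first alternatives were set before the data were examined.

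The alternatives were DESeq2 1.42.0, RLE scaling, no filter, unstranded counts, no run term, the replicate number as a block, and leaving out each library. Added after the data were examined were the contrast of exercise against enriched housing, tests of whether a change differed between regions (with group and number as a block), a fit without the libraries with Ttr above 1000, Gm42418 above 3000 or Cbln3 above 10 CPM (4, 9 and 3 libraries in the 3 regions), and a fit with the mean levels of 5 cell type lists as covariates. The methods were tested on simulated data with 200 changed genes. For labelled CREB -/- against wildtype, edgeR found 70% of genes changed 1.5-fold and 90.8% of those changed 2-fold in the dorsal dentate gyrus (16425 genes), 66% and 82.7% in the ventral dentate gyrus (16847 genes) and 71.1% and 87.9% in the visual cortex (16642 genes). Figures were drawn with matplotlib. A few named genes that the rule gave are not reported here.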

Results

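RNA was sequenced from 3 brain regions of mice, the dorsal dentate gyrus, the ventral dentate gyrus and the visual cortex. The dentate gyrus is the part of the hippocampal formation in which granule neurons are added through adult life, and its dorsal and ventral ends have different connections. The libraries carried 3 genotype labels, wildtype, CREB +/- and CREB -/-, CREB being the transcription factor encoded by Creb1 that is activated through cAMP and calcium signalling. They also carried 3 housing labels, control, enriched and exercise. The series title places the comparisons in the question of what structural brain plasticity requires genetically and behaviourally. All combinations gave 27 groups of 4 to 6 libraries and 135 libraries in all, 45 per region, of which 13 were labelled wildtype, 17 CREB +/- and 15 CREB -/-. By housing, 15 libraries per region were from control, 16 from enriched and 14 from exercise animals. The libraries held between 6.37 and 17.1 M counts in genes, with a median of 11.3 M, and gene levels are given as CPM, counts scaled to library size. They came from 2 sequencing runs, a shallower run of 60 libraries (median 9.40 M) and a deeper run of 75 (median 12.7 M). All libraries labelled CREB -/- from control and enriched housing were in the shallower run. All wildtype control and exercise libraries were in the deeper run, so run was a term in each model. The labels do not say that libraries are from separate animals, so p-values measure the spread between these libraries.

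Creb1 itself (ENSMUSG00000025958, chromosome 1, 64532645 to 64604548, plus strand, mm10) was read first as a check of the genotype labels. Its counts rose, and did not fall, with the labelled loss of alleles. In the dorsal dentate gyrus Creb1 stood at 98.6 ± 7.18 CPM (SD, n = 13) in wildtype, 144 ± 11.2 (n = 17) in CREB +/- and 199 ± 28.0 (n = 15) in libraries labelled CREB -/-. The corresponding levels were 92.3 ± 5.86, 138 ± 15.2 and 184 ± 27.9 in the ventral dentate gyrus and 98.7 ± 8.32, 149 ± 15.6 and 224 ± 35.5 in the visual cortex. Against wildtype, the log2 change of Creb1 in the libraries labelled CREB -/- was 1.0 ± 0.08 (SE, edgeR adjusted p = 7.5e-11), 0.92 ± 0.09 (adjusted p = 1.55e-08) and 1.09 ± 0.10 (adjusted p = 1.92e-10) in the 3 regions in that order. Crem, a related cAMP-responsive factor, also rose, by 0.89 ± 0.12, 0.97 ± 0.12 and 0.64 ± 0.10. Atf1, the other close relative, did not pass the test (0.0025 ± 0.12, 0.24 ± 0.11 and 0.03 ± 0.12). Counts per gene do not show which exons were transcribed, so they cannot tell a changed transcript from an intact one. Because Creb1 counts go against a plain reading of the label, the genotype is written as labelled CREB -/- throughout, and each direction below rests on that label. Enriched replicate 1 of this label had Creb1 at 113, 111 and 108 CPM in the 3 regions. The lowest other library of the label had 180, 156 and 204, and the highest wildtype library 114, 98.9 and 113.

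**Figure D1:**
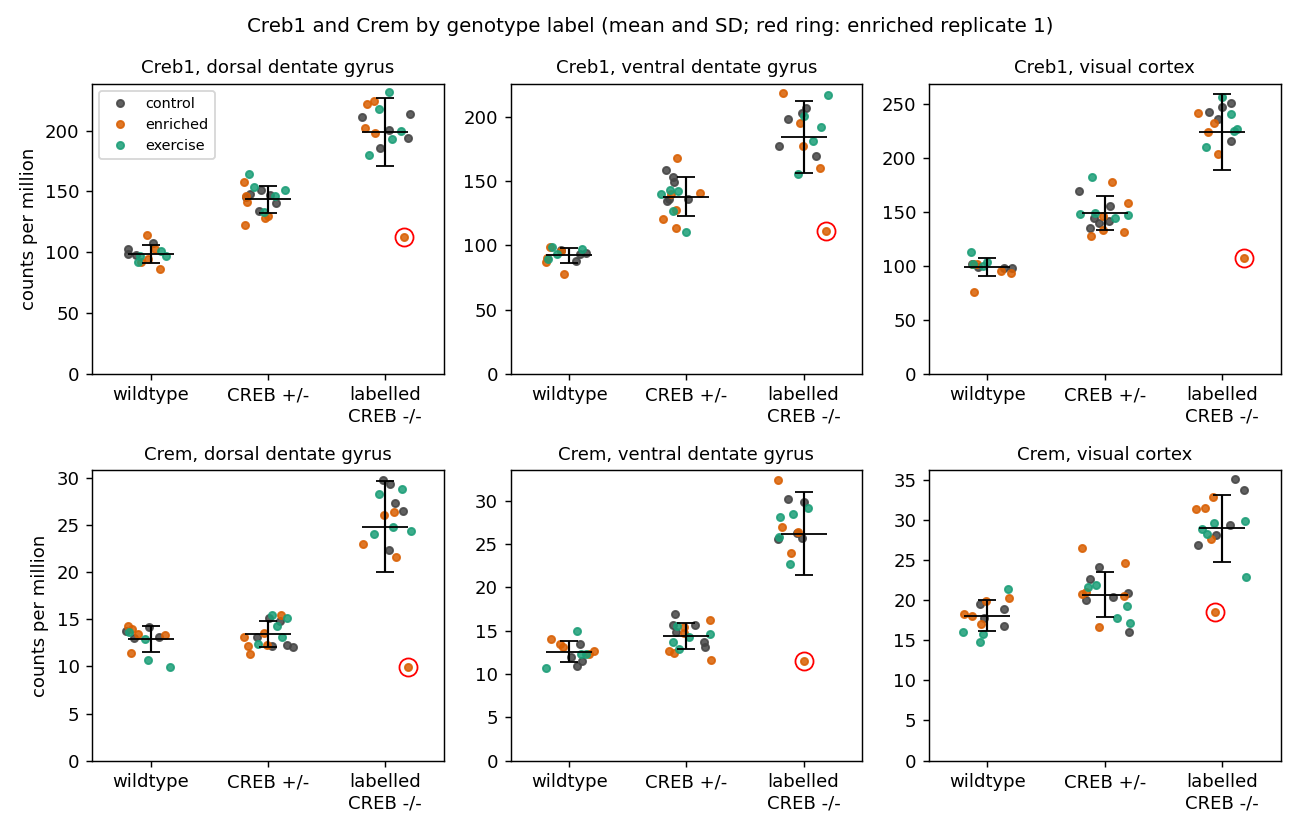
Creb1 (upper panels) and Crem (lower panels) in CPM for each library by genotype label, in the dorsal dentate gyrus, ventral dentate gyrus and visual cortex (n = 13, 17 and 15 libraries per region). Points are libraries coloured by housing, bars are the mean and SD, and the red ring marks labelled CREB -/- enriched replicate 1, whose Creb1 lies at 113, 111 and 108.

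In the dorsal dentate gyrus, libraries labelled CREB -/- had more RNA of Zbtb21, a zinc finger regulator of transcription (log2 change 0.61 ± 0.07 SE, edgeR adjusted p = 8.88e-08), Pdcd11, needed for ribosomal RNA processing (0.47 ± 0.06), and Mmab, an enzyme of cobalamin metabolism (0.61 ± 0.08). Also higher was Akap13, an anchoring protein for protein kinase A (0.46 ± 0.06). They had less of Nbdy, a small protein of P-bodies (-1.08 ± 0.09, adjusted p = 1.36e-10), Zfp367 (-1.28 ± 0.13), and Cep295, a centriole protein (-0.78 ± 0.08). Further lower genes were Mr1, which presents vitamin metabolites to T cells (-1.71 ± 0.18), Adipor1, an adiponectin receptor (-0.55 ± 0.06), Stxbp2, which acts in vesicle fusion (-0.89 ± 0.10), and the cytokine Il18 (-0.74 ± 0.09). H2-T22, which shares sequence with its paralogs in the major histocompatibility complex and is therefore uncertain, was also lower (-1.04 ± 0.12). Among markers of immature granule neurons, 3 of 13 rose, namely Igfbpl1 (0.84 ± 0.22), Dcx (0.46 ± 0.13) and Dpysl3 (0.28 ± 0.08), also 3 adjusted over the list alone. Of 11 astrocyte markers 4 fell (9 adjusted over the list alone), including the gap junction proteins Gja1 (-0.48 ± 0.11) and Gjb6 (-0.42 ± 0.11), the water channel Aqp4 (-0.44 ± 0.12) and Fgfr3 (-0.30 ± 0.09). Of 12 microglial markers 5 fell (11 adjusted over the list alone), including Csf1r (-0.50 ± 0.11), Itgam (-0.55 ± 0.13) and Cx3cr1 (-0.39 ± 0.11). As sets the 3 lists had camera adjusted p = 0.0188, 2.82e-07 and 1.47e-09. None passed otherwise (adjusted p = 0.428, 0.344 and 0.344 with an estimated correlation), and the immature neuron set also lost its call without the libraries of high Gm42418. Endothelial (camera adjusted p = 0.0166), mitochondrially encoded (0.0166) and meningeal genes (0.0188) were lower as sets in the same libraries (adjusted p = 0.911, 0.911 and 0.865 with an estimated correlation). Of these 1 of 15, 1 of 12 and 0 of 11 passed over all genes, and 4, 2 and 0 adjusted over the list alone. Of 25 immediate early genes, Fosl2 (0.45 ± 0.14) and Bdnf (0.30 ± 0.09) rose and Nr4a2 (-0.68 ± 0.19) fell, with 2 and 1 adjusted over the list alone. The set did not pass (camera adjusted p = 0.582). Single members of other lists that changed were Stra6, a retinol transporter of dorsal granule cells (0.85 ± 0.14), Acan, the core proteoglycan of perineuronal nets (0.56 ± 0.12), and Pcsk1, a processing protease of neuropeptides (-0.56 ± 0.13). Over all genes, 677 of 16691 genes passed the edgeR threshold, 259 higher and 418 lower. Within the deeper run, where only exercise libraries of both labels occur (2 labelled CREB -/- and 4 wildtype), 666 of the 677 kept their sign, with a median size of 0.284 against 0.405 in the full model, although these libraries also entered the model that chose the genes. The count was 254 with the cell type covariates (195 of the 677 among them), 1533 without the run term and 1158 without labelled CREB -/- exercise replicate 4.

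The ventral dentate gyrus libraries labelled CREB -/- again had more Zbtb21 (0.67 ± 0.07, edgeR adjusted p = 1.55e-08) and Pdcd11 (0.40 ± 0.06). They also had more of the synaptic receptor tyrosine kinase Ephb2 (0.42 ± 0.07), the histone chaperone Dnajc9 (0.42 ± 0.07), the laminin receptor subunit Itga7 (0.77 ± 0.13) and the secreted Lgi3 (0.48 ± 0.08). Lower genes were Nbdy (-0.99 ± 0.10), the co-chaperone Bag2 (-1.38 ± 0.14, adjusted p = 3.6e-08), Mr1 (-1.46 ± 0.20) and the kinase Alpk1 (-1.44 ± 0.20). The mitochondrial aminotransferase Oat (-0.47 ± 0.06) and H2-T10 (-2.51 ± 0.35), again a gene with close paralogs, were lower too. Of 12 genes of mature oligodendrocytes, which make myelin, 2 rose (12 adjusted over the list alone), Mag (0.94 ± 0.27) and Cnp (0.83 ± 0.23), as did Enpp6 of newly formed oligodendrocytes (1.17 ± 0.34). The mature oligodendrocyte set passed with the preset correlation (camera adjusted p = 1.2e-07) but not otherwise (adjusted p = 0.676 with an estimated correlation). Other sets moved too, among them lower microglial genes (camera adjusted p = 0.00658) and nuclear genes of oxidative phosphorylation (0.00324) and higher oligodendrocyte precursor genes (0.0185). The oxidative phosphorylation and precursor sets lost the call with no run term. With an estimated correlation none of these sets passed. Of 18 neuropeptide and secretory granule genes 1 rose and 4 fell (2 and 4 adjusted over the list alone). Nts was higher (3.41 ± 0.84) at low and variable levels of 12.6 ± 9.71 CPM against 6.01 ± 10.7 in wildtype. Cck (-0.66 ± 0.16), Sst (-0.87 ± 0.26), Gal (-2.44 ± 0.73) and Npy (-0.48 ± 0.15) were lower. Acan (1.46 ± 0.26) and the aggrecan-cleaving protease Adamts4 (0.98 ± 0.25) rose, as did Stra6 (0.91 ± 0.20) and Gsg1l (1.08 ± 0.28), 2 of 4 dorsal dentate genes (4 adjusted over the list alone). Fosl2 (0.78 ± 0.21) and Egr3 (0.47 ± 0.13) were 2 of 25 immediate early genes that rose (3 adjusted over the list alone). The microglial P2ry12 (-0.44 ± 0.11), the astrocytic Gja1 (-0.35 ± 0.10), Nlgn1, an adhesion molecule of synapses (-0.35 ± 0.09), and the glutamate receptor subunit Gria2 (-0.21 ± 0.06) fell. The dorsal dentate set (camera adjusted p = 0.00658) and the immediate early set (0.0247) did not pass otherwise (both adjusted p = 0.676 with an estimated correlation). In the same libraries Slc17a6, a vesicular glutamate transporter of thalamic and other projection neurons chosen here after its values were seen, was higher by 2.38 ± 0.67 (adjusted p = 0.0265). Ttr, an abundant choroid plexus transcript with a median of 6.79 CPM, reached 3935 in a wildtype, 2112 in a CREB +/- and 3757 in a labelled CREB -/- library. All 12 choroid plexus genes had a positive change (median 2.19), with none past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.12). In all, 1133 of 17080 genes passed, 587 higher and 546 lower, and within the deeper run 1132 of them kept their sign, with a median size of 0.467 against 0.403. The count was 1869 with the cell type covariates (690 of the 1133 among them), 3028 without the 9 libraries with high Ttr or Gm42418, and 723 without a filter on low counts. It was 424 to 733 without any of labelled CREB -/- exercise replicate 4 (lowest), CREB +/- exercise replicate 4, CREB +/- enriched replicate 6 and wildtype control replicate 1 (highest). It was 1914 without CREB +/- enriched replicate 2.

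Visual cortex libraries labelled CREB -/- had more of the co-chaperone Dnajb2 (0.50 ± 0.06, edgeR adjusted p = 3.56e-07), Dnajc9 (0.50 ± 0.06), Zbtb21 (0.57 ± 0.07), Lgi3 (0.43 ± 0.05) and the interferon-inducible Ifi27 (0.65 ± 0.10). Dnajb2 lies within 20 Mb of Creb1, so a variant carried along with that locus stays open for it. Lower genes were Alpk1 (-1.79 ± 0.13, adjusted p = 3.02e-13), Zfp367 (-1.09 ± 0.09), Cep295 (-0.58 ± 0.06) and Mr1 (-2.07 ± 0.22). H2-T22 (-1.22 ± 0.14), Nbdy (-1.01 ± 0.13), Camk1, a calcium-dependent kinase (-0.74 ± 0.10), and the glutathione transferase Gstm4 (-1.08 ± 0.13) were lower too. Of 12 mature oligodendrocyte genes 5 rose (10 adjusted over the list alone), including Mag (0.77 ± 0.18), Mog (0.67 ± 0.19), Cnp (0.66 ± 0.15) and Mal (0.61 ± 0.17). Of 11 astrocyte genes 3 fell and 1 rose (4 and 1 adjusted over the list alone), namely Aqp4 (-0.67 ± 0.12), Gja1 (-0.45 ± 0.09), the glutamate transporter Slc1a2 (-0.23 ± 0.07) and Aldh1l1 (0.26 ± 0.07). The oligodendrocyte set had camera adjusted p = 1.66e-07 and the astrocyte set 0.00486. Neither passed otherwise (both adjusted p = 0.548 with an estimated correlation). Other sets moved too, among them lower meningeal (camera adjusted p = 0.00486) and mitochondrially encoded genes (0.017) and higher nuclear genes of oxidative phosphorylation (0.0167). The meningeal and mitochondrially encoded sets lost the call with no run term. With an estimated correlation none of these sets passed. The granule proteins Chga (0.51 ± 0.12) and Vgf (0.44 ± 0.13) rose, as did the respiratory chain genes Uqcrc1 (0.26 ± 0.07) and Cox5a (0.21 ± 0.06). The mitochondrially encoded mt-Nd6 (-0.74 ± 0.17) and the microglial Csf1r (-0.21 ± 0.06) fell. Matrix genes went both ways, with Adamts4 (0.81 ± 0.19) and Hapln4 (0.39 ± 0.12) higher and Tnc (-0.88 ± 0.24) lower. In all, 820 of 16849 genes passed, 425 higher and 395 lower, and 817 kept their sign within the deeper run, with a median size of 0.395 against 0.338. The count was 399 with the cell type covariates (224 of the 820 among them), 1868 without the run term, 410 without labelled CREB -/- exercise replicate 4 and 1250 without CREB +/- enriched replicate 2.

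Libraries labelled CREB +/- differed from wildtype in few genes, Creb1 first among them. Its log2 change was 0.54 ± 0.06 (SE, edgeR adjusted p = 1.9e-06) in the dorsal dentate gyrus, 0.54 ± 0.07 in the ventral dentate gyrus and 0.56 ± 0.07 in the visual cortex (n = 17 against 13). Crem (0.04 ± 0.09, 0.16 ± 0.09 and 0.18 ± 0.08) and Atf1 (0.08 ± 0.08, 0.18 ± 0.09 and 0.01 ± 0.08) did not pass in any region. In the dorsal dentate gyrus 6 genes passed, and the 5 that were lower, Gm13205 (-1.51 ± 0.26), Gm15564 (-5.14 ± 0.90), Lars2 (-2.81 ± 0.52), Mir6236 (-2.70 ± 0.52) and Gm42418 (-2.25 ± 0.46), were named after their values were seen. Gm42418 overlaps ribosomal RNA repeats and Lars2 shares such sequence, so these counts are uncertain, and Gm15564 reached 197 CPM in a single wildtype library. In the ventral dentate gyrus Zbtb21 rose (0.27 ± 0.05, adjusted p = 0.0321) and the signalling ligand Lefty1 fell (-1.93 ± 0.36, adjusted p = 0.0321) beside Creb1, 3 genes in all. Gm13205 (-1.08 ± 0.19, adjusted p = 0.0103) was the only gene past the threshold beside Creb1 in the visual cortex. Of 12 mature oligodendrocyte genes in the visual cortex, none passed over all genes and 9 were higher adjusted over the list alone (camera adjusted p = 1.05e-09, adjusted p = 0.217 with an estimated correlation). In the dorsal dentate gyrus the same set was lower (0 of 12 over all genes and adjusted over the list alone, median -0.13, camera adjusted p = 0.00121, adjusted p = 0.662 with an estimated correlation). It was higher in the ventral dentate gyrus (0 of 12 over all genes and adjusted over the list alone, camera adjusted p = 0.00821, adjusted p = 0.682 with an estimated correlation). Other cell type sets moved too, among them lower dorsal microglial (camera adjusted p = 9.06e-05) and astrocyte genes (0.000329) and lower cortical meningeal (3.28e-05) and astrocyte genes (0.000509). None of these 4 kept its call (adjusted p = 0.624, 0.624, 0.359 and 0.217 with an estimated correlation), and 0 members passed over all genes, with 3 cortical astrocyte genes lower adjusted over the list alone. The dorsal count was 2 without the 4 libraries of high Gm42418, 2 without wildtype control replicate 1 or wildtype enriched replicate 4, and 10 without labelled CREB -/- exercise replicate 4.

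Between control and enriched housing, averaged over the genotypes, Npy, which encodes neuropeptide Y, rose in the dorsal dentate gyrus from 28.6 ± 5.04 (SD, n = 15) to 49.6 ± 9.78 CPM (n = 16). This was a log2 change of 0.82 ± 0.10 (SE, edgeR adjusted p = 1.34e-05). Penk, the enkephalin precursor, rose from 23.2 ± 3.65 to 35.7 ± 5.91 (0.59 ± 0.09, adjusted p = 0.00148). Other genes that rose were Mylk3, a myosin kinase (0.70 ± 0.12), Actn3, an actinin (0.98 ± 0.17), Nhlh1, a neuronal basic helix-loop-helix factor (0.86 ± 0.16), Tnnt2 (0.90 ± 0.18), and the guidance receptor Robo3 (0.47 ± 0.09). Ranbp3l (-0.63 ± 0.11), the glial phosphatase receptor Ptprz1 (-0.23 ± 0.05), Apoe, the lipid carrier made mainly by astrocytes (-0.34 ± 0.07), Pdgfra of oligodendrocyte precursors (-0.27 ± 0.06), and the protocadherin Pcdh9 (-0.15 ± 0.03) fell. Of 25 immediate early genes, which neurons transcribe rapidly on activity, 5 rose (10 adjusted over the list alone), among them Gadd45b (0.35 ± 0.07), Fosl2 (0.41 ± 0.10), Nptx2 (0.40 ± 0.10) and Fosb (0.66 ± 0.18). The neurotrophin Bdnf rose (0.23 ± 0.06, adjusted p = 0.047). The values of Fos (0.66 ± 0.18, adjusted p = 0.0508), Arc (0.23 ± 0.13, adjusted p = 0.351), Dcx (0.11 ± 0.09, adjusted p = 0.595) and the proliferation marker Mki67 (0.18 ± 0.09, adjusted p = 0.299) did not pass. Npy and Penk were 2 of 16 neuropeptide genes that rose (5 adjusted over the list alone), and Igfbpl1 (0.65 ± 0.16) was 1 of 13 immature neuron genes (2 adjusted over the list alone). In the same libraries 3 of 11 astrocyte genes fell (5 adjusted over the list alone), Gja1 (-0.34 ± 0.08), Aqp4 (-0.37 ± 0.09) and Slc1a3 (-0.24 ± 0.06). Of 12 microglial genes 2 fell (7 adjusted over the list alone), P2ry12 (-0.43 ± 0.11) and Csf1r (-0.28 ± 0.07). Of 12 mitochondrially encoded genes 2 fell (10 adjusted over the list alone), mt-Nd4 (-0.54 ± 0.14) and mt-Cytb (-0.48 ± 0.12). Camera gave adjusted p = 1.41e-07 for immediate early, 0.00137 for neuropeptide, 0.000497 for immature neuron, 2.81e-07 for astrocyte, 2.81e-07 for microglial and 1.41e-07 for mitochondrially encoded genes. None of these sets passed otherwise (adjusted p = 0.218 for the first 3 and 0.241 for the last 3 with an estimated correlation). Endothelial (camera adjusted p = 8.18e-06), mature oligodendrocyte (0.000148) and oligodendrocyte precursor genes (0.00154) were lower and granule cell genes (0.00124) higher as sets (adjusted p = 0.296, 0.392, 0.377 and 0.392 with an estimated correlation). Of these 1 of 15, 0 of 12, 1 of 12 and 1 of 14 passed over all genes, and 5, 0, 1 and 1 adjusted over the list alone. Single members of other lists that changed were the heat shock protein Hsph1 (0.24 ± 0.05), Arl4d (0.39 ± 0.08), Acan (0.35 ± 0.08), Hapln1 (-0.42 ± 0.11) and Dsp (0.34 ± 0.08).

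In all, 261 of 16691 genes passed for enriched housing in the dorsal dentate gyrus, 149 higher and 112 lower. The count was 565 by DESeq2, 75 without the run term and 14 when the mean levels of 5 cell type lists were covariates, of which 11 were among the 261. Leaving out 1 library at a time moved it to between 40 and 173 without CREB +/- control replicate 4 or 5, CREB +/- enriched replicate 2, 4 or 6, labelled CREB -/- control replicate 1 or 2, labelled CREB -/- enriched replicate 1 or 4, wildtype control replicate 2 or 3, or wildtype enriched replicate 1 or 2. It moved to between 392 and 546 without CREB +/- enriched replicate 21 or 3, labelled CREB -/- enriched replicate 3, labelled CREB -/- exercise replicate 4 or wildtype enriched replicate 3. With the covariates 11 of the 261 genes stayed called, so cell composition of the tissue pieces may account for part. The covariates may themselves carry the housing effect, so this cannot be told apart.

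In the ventral dentate gyrus the changes of Fosb (0.88 ± 0.18, edgeR adjusted p = 0.0727), Vgf (0.57 ± 0.12, adjusted p = 0.107) and Npy (0.46 ± 0.11, adjusted p = 0.166) with enriched housing did not pass. Nor did those of Fos (0.76 ± 0.28), Arc (0.45 ± 0.22), Bdnf (0.17 ± 0.08), Dcx (0.10 ± 0.07) and Mki67 (-0.22 ± 0.16). In the ventral dentate gyrus 0 genes passed with edgeR, 2405 had an unadjusted p under 0.05, and DESeq2 called 23. On simulated counts of this contrast edgeR found 70.7% of genes changed 1.5-fold and 94.8% of those changed 2-fold. These shares need not hold for the real libraries, where leaving out 1 library moved the count from 0 to 164. Adjusted over the list alone, 7 of 25 immediate early genes were higher, and the set had camera adjusted p = 1.32e-08 (adjusted p = 0.442 with an estimated correlation). All 12 choroid plexus genes had a positive change (median 1.18, camera adjusted p = 0.00576, adjusted p = 0.673 with an estimated correlation), with none passing over all genes or adjusted over the list alone. Among other ventral sets, granule cell (camera adjusted p = 0.000669), mitochondrially encoded (0.00909) and mature oligodendrocyte genes (0.0196) were lower and heat shock (2.59e-05) and interneuron genes (0.00909) higher. None of these 5 kept its call (adjusted p = 0.597, 0.637, 0.716, 0.442 and 0.442 with an estimated correlation). Over all genes 0 of their members passed, and adjusted over the list alone 4 of 12 heat shock genes were higher and 2 of 12 interneuron genes higher and 1 lower. Without labelled CREB -/- control replicate 2, 164 genes passed. In the visual cortex Fam107a, an actin-associated protein that responds to stress hormones, rose (0.29 ± 0.05, adjusted p = 0.0132) and Zfp882 fell (-0.39 ± 0.07, adjusted p = 0.0192), and these were the 2 genes that passed with edgeR. Neither passed without the 3 libraries of high Gm42418 or Cbln3. DESeq2 called 12 genes there, and 644 passed with the cell type covariates. Values of Bdnf (0.18 ± 0.10), Dcx (0.17 ± 0.10), Mki67 (0.23 ± 0.22), Fos (0.47 ± 0.28) and Arc (0.34 ± 0.31) did not pass. Of 25 immediate early genes, 1 was higher adjusted over the list alone and the set had camera adjusted p = 4.13e-06 (adjusted p = 0.711 with an estimated correlation). In the same contrast mitochondrially encoded genes were lower as a set (0 of 12 over all genes and adjusted over the list alone, median -0.24, camera adjusted p = 0.000571, adjusted p = 0.711 with an estimated correlation). Genes of oligodendrocyte precursors were higher as a set (median 0.16, camera adjusted p = 0.00123, adjusted p = 0.22 with an estimated correlation), with 0 of 12 over all genes and 4 adjusted over the list alone.

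**Figure D2:**
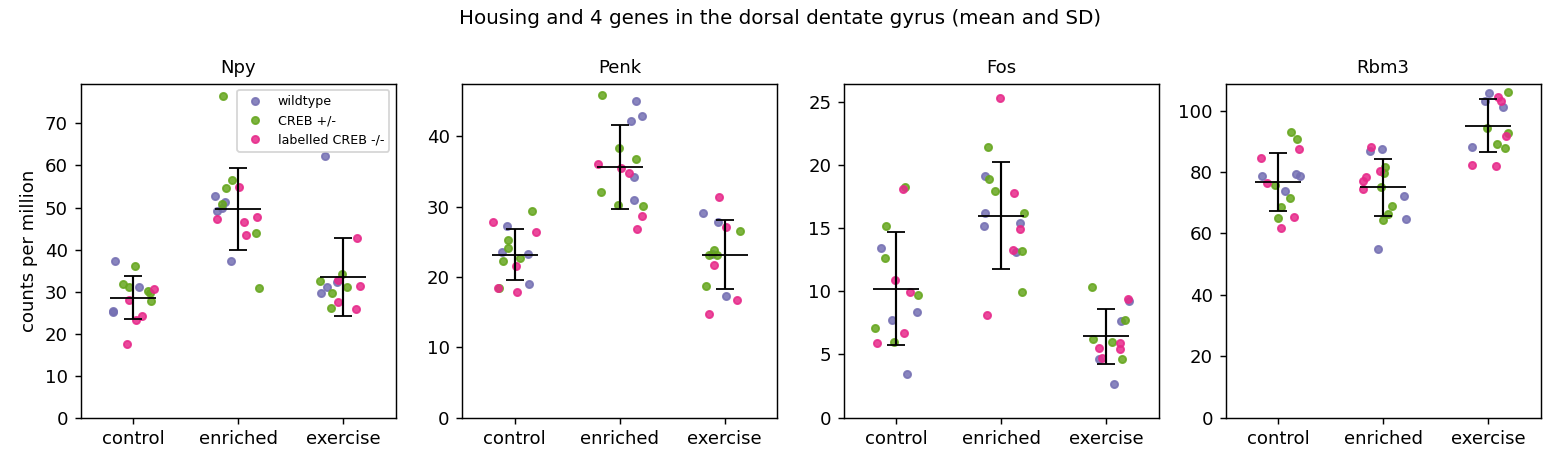
CPM of Npy, Penk, Fos and Rbm3 in each dorsal dentate gyrus library by housing (n = 15 control, 16 enriched and 14 exercise), coloured by genotype label, with mean and SD. Npy averaged 28.6, 49.6 and 33.5 and Rbm3 76.7, 75.0 and 95.1 in the 3 housing groups.

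Exercise against control housing changed few genes. In the visual cortex Rbm3, an RNA-binding protein induced by cold, rose (0.34 ± 0.06 SE, edgeR adjusted p = 0.005, n = 14 against 15). It was the only gene called there by edgeR, with 920 genes at an unadjusted p under 0.05 and 2 called by DESeq2. In the dorsal dentate gyrus Bdnf (-0.02 ± 0.06), Dcx (0.06 ± 0.09), Mki67 (0.04 ± 0.09), Fos (-0.64 ± 0.20), Arc (-0.32 ± 0.13) and the activity-dependent factor Npas4 (-1.12 ± 0.21, adjusted p = 0.0744) did not pass. The edgeR count was 0, with 979 genes at an unadjusted p under 0.05 and 2 called by DESeq2. All 15 glucocorticoid response genes had a negative change there (median -0.18). Of these 4 were lower adjusted over the list alone, among them the kinase Sgk1 (-0.21 ± 0.06) and the metallothionein Mt2 (-0.38 ± 0.11), and 0 passed over all genes. This set passed both ways (camera adjusted p = 6.34e-08, adjusted p = 0.00406 with an estimated correlation). Other sets were lower in the same libraries, among them endothelial and pericyte (camera adjusted p = 6.34e-08), mitochondrially encoded (0.000156) and astrocyte genes (0.000557). None of these kept its call (adjusted p = 0.352, 0.482 and 0.482 with an estimated correlation). Over all genes 0 of their members passed, and adjusted over the list alone 3 of 15, 0 of 12 and 0 of 11 were lower. The glucocorticoid set gave adjusted p = 6.13e-06 in the ventral dentate gyrus and 1.56e-07 in the visual cortex, but there adjusted p = 0.109 and 0.0659 with an estimated correlation. Other ventral sets moved as well, and among them blood cell (camera adjusted p = 2.53e-05), mature oligodendrocyte (1.78e-05) and meningeal genes (0.00319) were lower and synaptic genes (3.77e-05) higher. None of these 4 kept its call (adjusted p = 0.421, 0.546, 0.501 and 0.501 with an estimated correlation), and 0 members passed over all genes, with 4 of 5 blood cell and 1 of 11 meningeal genes lower adjusted over the list alone. Of 25 immediate early genes, 6 were lower adjusted over the list alone in the dorsal dentate gyrus (camera adjusted p = 6.98e-06, adjusted p = 0.352 with an estimated correlation). The immediate early set was lower in the visual cortex as well (0 of 25 over all genes and adjusted over the list alone, camera adjusted p = 2.22e-09, adjusted p = 0.312 with an estimated correlation), and was not called in the ventral dentate gyrus. Cortical heat shock (camera adjusted p = 0.00179) and neuropeptide genes (0.000471) were also lower as sets (adjusted p = 0.113 and 0.112 with an estimated correlation), with 0 over all genes and 1 each adjusted over the list alone. In the ventral dentate gyrus the values were -0.0017 ± 0.08 for Bdnf, 0.09 ± 0.07 for Dcx, 0.0044 ± 0.15 for Mki67, -0.46 ± 0.29 for Fos and -0.16 ± 0.22 for Arc. The same genes in the visual cortex had -0.07 ± 0.10, -0.04 ± 0.10, 0.06 ± 0.23, -0.52 ± 0.28 and -0.63 ± 0.31. The ventral count was 0 with edgeR and with DESeq2, with 1192 genes at an unadjusted p under 0.05.

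Exercise against enriched housing was compared after the data were examined. Of the dorsal dentate gyrus genes, Npas4 (-1.55 ± 0.21, edgeR adjusted p = 4.46e-05), Egr2 (-1.58 ± 0.24), Fos (-1.31 ± 0.19) and Fosb (-1.09 ± 0.18) were lower in exercise. Fos averaged 6.43 ± 2.17 CPM against 15.99 ± 4.21 (SD, n = 14 and 16). Penk (-0.60 ± 0.09), Npy (-0.56 ± 0.10), Arl4d (-0.48 ± 0.08), Hsph1 (-0.30 ± 0.05) and Sgk1 (-0.23 ± 0.06) were lower too. Rbm3 (0.35 ± 0.06, adjusted p = 0.00187), the clock output gene Dbp (0.46 ± 0.09), the carbonic anhydrase Car2 (0.40 ± 0.09) and the growth factor Ptn (0.33 ± 0.08) were higher. Of 25 immediate early genes 7 fell (18 adjusted over the list alone) and none rose (camera adjusted p = 4.21e-22, adjusted p = 0.00105 with an estimated correlation). In the ventral dentate gyrus Fosb (-1.03 ± 0.18, adjusted p = 0.0161), Egr2 (-1.49 ± 0.28) and Lcn2, an iron-binding protein of inflammation (-5.33 ± 0.92, at most 7.26 CPM in enriched and 0.930 in exercise libraries), fell. Rbm3 (0.38 ± 0.07) and the clock gene Ciart (0.59 ± 0.12, adjusted p = 0.05) rose. Choroid plexus genes were lower in the same libraries, 0 of 12 past the threshold over all genes and 9 adjusted over the list alone (camera adjusted p = 1.68e-06, adjusted p = 0.375 with an estimated correlation). In this region 2 immediate early genes fell (13 adjusted over the list alone, camera adjusted p = 1.47e-17, adjusted p = 0.0132 with an estimated correlation). In the visual cortex Hsph1 (-0.35 ± 0.04, adjusted p = 1.03e-06), Fam107a (-0.42 ± 0.05), Fosl2 (-0.87 ± 0.15), Fosb (-0.84 ± 0.17), Gadd45b (-0.61 ± 0.13) and Nptx2 (-0.59 ± 0.13) fell. So did Vgf (-0.52 ± 0.10), Pcsk1 (-0.32 ± 0.08), Cdkn1a (-0.85 ± 0.16), Hspa1a (-0.47 ± 0.12), Plin4 (-1.04 ± 0.24), Ntrk2, the receptor of the Bdnf protein (-0.17 ± 0.04), and Hyou1 (-0.19 ± 0.04). Rbm3 (0.42 ± 0.06, adjusted p = 1.19e-05) and P2ry12 (0.34 ± 0.07) rose. There 7 of 25 immediate early genes fell (22 adjusted over the list alone, camera adjusted p = 2.99e-18, adjusted p = 0.0632 with an estimated correlation). Glucocorticoid response genes were lower as a set in the dorsal (adjusted p = 7.77e-07, adjusted p = 0.00684 with an estimated correlation) and ventral dentate gyrus (8.74e-09, adjusted p = 0.0132 with an estimated correlation). In the visual cortex the set had 5.14e-06 (adjusted p = 0.0545 with an estimated correlation). In the 3 regions 2, 0 and 2 of 15 were past the threshold over all genes and 6, 6 and 8 adjusted over the list alone. Within each run the median change of the immediate early genes was negative in every region, from -0.149 in the ventral dentate gyrus in the shallower run to -0.71 in the visual cortex in the deeper run.

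For exercise against enriched housing, 72 genes passed in the dorsal dentate gyrus (20 higher and 52 lower), 5 in the ventral dentate gyrus and 125 in the visual cortex (43 higher and 82 lower). DESeq2 called 174, 14 and 386. Without the run term the edgeR counts were 38, 4 and 25, and without the libraries of high Ttr, Gm42418 or Cbln3 they were 78, 1 and 58. With the replicate block and the run term they were 158, 0 and 28. The dorsal count moved to between 28 and 47 without CREB +/- enriched replicate 5, CREB +/- exercise replicate 1 or 3, labelled CREB -/- enriched replicate 1 or 4, labelled CREB -/- exercise replicate 5 or wildtype exercise replicate 1 or 4. It moved to between 110 and 318 without CREB +/- enriched replicate 21 or 3, labelled CREB -/- enriched replicate 3, labelled CREB -/- exercise replicate 1 or wildtype exercise replicate 2. The cortical count moved to between 29 and 76 without CREB +/- enriched replicate 6, CREB +/- exercise replicate 1, labelled CREB -/- enriched replicate 2 or 4, labelled CREB -/- exercise replicate 5, wildtype enriched replicate 1 or wildtype exercise replicate 1 or 5. It moved to between 285 and 319 without CREB +/- enriched replicate 2 or 3 or labelled CREB -/- exercise replicate 2.

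Whether housing acted differently by genotype was tested within each genotype and by the interaction of both factors. Only Gm15564, a transcript of uncertain counting, passed. Its exercise change in CREB +/- libraries of the dorsal dentate gyrus was -8.18 ± 1.45 (SE, edgeR adjusted p = 0.0199, n = 5 against 6), and its interaction term had adjusted p = 0.00822. Group means of Gm15564 were 1.56 ± 1.91 CPM in CREB +/- control (SD, n = 6), 0.183 ± 0.145 in CREB +/- exercise (n = 5) and 40.2 ± 87.9 in wildtype enriched libraries (n = 5). Without the 4 dorsal libraries of high Gm42418 neither call held. Every other contrast within a genotype had 0 genes with edgeR in all 3 regions. For enriched housing, unadjusted p was under 0.05 for 878, 344 and 537 genes in wildtype in the dorsal and ventral dentate gyrus and visual cortex, 1328, 1668 and 1508 in CREB +/-, and 2507, 616 and 932 in libraries labelled CREB -/-. DESeq2 called 2, 0 and 0 genes, 0, 3 and 1, and 234, 0 and 0 in these. For exercise the unadjusted counts were 1002, 415 and 1621 in wildtype, 2271 and 1041 in the ventral dentate gyrus and visual cortex of CREB +/-, and 872, 710 and 781 under the label CREB -/-, and DESeq2 called 0 except for 21 in the ventral dentate gyrus of CREB +/-. The interaction gave 0 genes in the ventral dentate gyrus (505 at an unadjusted p under 0.05, 3 by DESeq2) and in the visual cortex (817 and 0). An effect called in the average over genotypes and not within a genotype is not shown to differ between genotypes.

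The dorsal dentate gyrus differed from the ventral in genes of several kinds. Itga7 was higher dorsally (57.0 ± 7.74 against 26.3 ± 7.16 CPM, SD, n = 45 each, log2 change 1.14 ± 0.04 SE, edgeR adjusted p = 3.2e-44). So were the kallikrein Klk10 (3.50 ± 0.17) and the desmosomal Pkp1 (3.98 ± 0.22) and Dsp (1.01 ± 0.10). The sialyltransferase St8sia6 (1.59 ± 0.08), the dorsal marker Lct (1.32 ± 0.09), Fam163b (1.10 ± 0.09), Acan (1.21 ± 0.08) and the activin subunit Inhba (1.37 ± 0.11) were higher dorsally. Higher ventrally were the netrin Ntn5 (-2.84 ± 0.13), the gastrin-releasing peptide gene Grp (-2.16 ± 0.10), and Resp18 (-1.65 ± 0.07). The thyrotropin-releasing hormone receptor Trhr (-3.79 ± 0.21), the transcription factor Nr2f2 (-1.97 ± 0.14), Efnb2 (-1.08 ± 0.06), Kit (-1.63 ± 0.09), Timp2 (-1.26 ± 0.07) and the kinase receptor Met (-1.45 ± 0.13) followed. The same held for the peptide genes Nts (-5.14 ± 0.39), Adcyap1 (-2.03 ± 0.14) and Vip (-1.17 ± 0.09), with Calb2 of mossy cells and interneurons (-2.47 ± 0.19). All 4 ventral dentate genes were higher ventrally (4 adjusted over the list alone, camera adjusted p = 4.26e-07, adjusted p = 0.0047 with an estimated correlation). Of 14 dentate granule cell genes 3 were higher dorsally (3 adjusted over the list alone), and the set passed with the preset correlation only (camera adjusted p = 1.91e-09, adjusted p = 0.189 with an estimated correlation). Interneuron genes were lower dorsally as a set (1 of 12, 1 adjusted over the list alone, camera adjusted p = 0.000373, adjusted p = 0.108 with an estimated correlation). Choroid plexus genes moved with the ventral libraries: 10 of 12 were higher there, with Ttr at -3.71 ± 0.80, Aqp1 at -2.50 ± 0.41 and F5 at -2.91 ± 0.49 (camera adjusted p = 0.0979). With |log2 change| of at least 1, 544 of 17955 genes passed, 95 higher dorsally and 449 ventrally, and 911 passed without a filter on low counts.

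The dentate gyrus, both ends averaged, differed from the visual cortex in genes of many kinds, among them those of its principal neurons and of cell division. The glutamate receptor subunit Gria1 (1.82 ± 0.02 SE, edgeR adjusted p = 2.1e-97, n = 90 against 45) and the mineralocorticoid receptor Nr3c2 (2.56 ± 0.04) were higher in the dentate gyrus. The serotonin receptor Htr4 (3.52 ± 0.05), the tryptophan-degrading enzyme Tdo2 (4.52 ± 0.11), Lct (4.52 ± 0.11) followed, as did Dock10 (2.66 ± 0.06), Tgfb2 (2.90 ± 0.06), the neurotrophin Ntf3 (3.35 ± 0.10) and the intermediate filament Gfap (2.42 ± 0.08). Of 14 dentate granule cell genes 9 were higher, of 16 cell division genes 6, among them Cenpf (1.85 ± 0.08), Top2a (1.82 ± 0.09) and Mki67 (1.61 ± 0.08). Igfbpl1 of immature neurons was higher by 4.85 ± 0.17, whereas Dcx was lower (-1.62 ± 0.04). Of 14 immature granule neuron genes 4 were higher and 3 lower, 4 and 3 adjusted over the list alone, and the set did not pass (camera adjusted p = 0.542). The visual cortex was higher in Arpp19 (-2.21 ± 0.03), in 9 of 14 cortical layer genes including Cux2 (-2.75 ± 0.06), Rorb (-2.38 ± 0.06) and Lamp5 (-2.09 ± 0.04). Of 12 interneuron genes 3 were higher in the visual cortex, among them Pvalb (-1.49 ± 0.05) and Vip (-2.75 ± 0.07), and 1 in the dentate gyrus, Adarb2 (1.54 ± 0.05). This set had camera adjusted p = 0.0231 (adjusted p = 0.338 with an estimated correlation). Of 25 immediate early genes 15 were higher in the visual cortex and 2 in the dentate gyrus, with Egr1 at -2.95 ± 0.09, Egr2 at -3.41 ± 0.14, Nr4a1 at -2.71 ± 0.11 and Homer1 at -1.43 ± 0.04. The granule cell (camera adjusted p = 1.08e-06), cell division (0.0254), cortical layer (0.00393) and immediate early sets (0.000315) passed with the preset correlation. They lost the call otherwise (adjusted p = 0.338, 0.338, 0.323 and 0.526 with an estimated correlation). Choroid plexus genes were higher in the dentate gyrus in 9 of 12 cases (9 adjusted over the list alone, median 1.87), though not as a set (camera adjusted p = 0.378). Oligodendrocyte precursor genes were higher as a set (1 of 12, 1 adjusted over the list alone, camera adjusted p = 0.0231, adjusted p = 0.586 with an estimated correlation). Circadian clock genes were lower (4 of 15, 4 adjusted over the list alone, camera adjusted p = 0.00183, adjusted p = 0.338 with an estimated correlation). All 12 mature oligodendrocyte genes had a positive change (median 0.45), with 0 past the threshold either way. In all, 2278 of 17955 genes passed with |log2 change| of at least 1, 1012 higher in the dentate gyrus and 1266 in the visual cortex.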

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

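The tests of a wrong label and of a swap for labelled CREB -/- enriched replicate 1, its genotype score, the tests of differences between regions and every test of exercise against enriched housing were chosen after the result was seen. A first genotype score that used every called gene was replaced, after it was seen, by one of 20 genes, and its values are given below.

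Creb1 of labelled CREB -/- enriched replicate 1 lay far from the other libraries of its group at 112.8 CPM in the dorsal dentate gyrus and 107.7 in the visual cortex. On a score of 20 genes, with 0 the wildtype mean and 1 the mean of libraries labelled CREB -/-, its 3 libraries had 0.247, 0.112 and 0.176. The highest wildtype scores were 0.165, 0.12 and 0.0577, and the highest CREB +/- scores 0.234, 0.346 and 0.311. This score therefore does not single out wildtype, whereas its Creb1 lay below the lowest CREB +/- library dorsally (122.5) and in the visual cortex (127.5). On the first score its libraries had 0.683, -0.16 and 0.55. The lowest other library of the label had 0.716, 0.266 and 0.654, and CREB +/- libraries reached 0.71, 1.23 and 0.801. A swap needs a partner out of place, and Creb1 reached at most 113.8, 98.89 and 112.8 CPM in wildtype and 164, 168.3 and 182.3 in CREB +/- libraries against at least 180.2, 155.6 and 203.8 in the other labelled CREB -/- libraries, which argues against it, although the CREB +/- range overlaps ventrally, and the highest mean 20-gene score of 0.268 was not used, as wildtype libraries helped to pick its genes. Low depth is argued against by its lowest total of 7.22 M counts, within the range of other libraries. A single wrong genotype label may be the cause and stays open, and no biological explanation was tested. Without this replicate, labelled CREB -/- against wildtype had 677, 1584 and 817 called genes in the 3 regions (677, 1133 and 820 with it). Dorsal enriched housing then had 96 (261 with it). Exercise against enriched housing had 47, 3 and 99 (72, 5 and 125 with it).

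In the main edgeR fit the number of genes called between labelled CREB -/- and wildtype was larger than for any other contrast within a region. With cell type covariates the visual cortex had 399 against 644 for enriched housing. With the replicate block and the run term the dorsal dentate gyrus had 566 against 604 for enriched housing. A run difference that acts alike in all groups is argued against as the whole cause, since the run term did not end the pattern. That term took the count from 1533 to 677 in the dorsal dentate gyrus and from 1868 to 820 in the visual cortex. In the ventral dentate gyrus it raised the count, from 926 to 1133. A run effect that differs between groups stays open. The median change within the deeper run was at least 69.9% of that in the full model but decides little, as its 2 and 4 libraries helped to choose the genes. Variants near Creb1 are argued against as the whole cause, since at most 2.33% of called genes lay within 20 Mb of it. That highest share was in the visual cortex, where 1.54% of all tested genes lay there. Cell composition of the tissue pieces may account for part: with cell type covariates, at least 27.3% of the called genes stayed called, and the covariates themselves may carry the genotype effect, so this cannot be told apart, and a background difference elsewhere in the genome and the mutation itself stay open as untested.

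Lower immediate early genes and higher Rbm3 in exercise than in enriched housing was the third pattern. A run difference is argued against for the immediate early genes, since their highest within-run median was -0.149. Rbm3 was not examined within runs, so a run difference stays open for it. Another time of day at collection stays open. The mean change of Arntl, Npas2 and Clock, which it would lower, was -0.0777 ± 0.0412, -0.0488 ± 0.0575 and -0.0948 ± 0.0325 (SE) in the 3 regions. This SE takes the 3 genes as independent. The mean was negative in each region and beyond 2 SE in the visual cortex alone, and Clock itself was positive in each. The clock genes Dbp, Ciart, Tef, Nr1d2 and Per3 had positive changes of at least 0.0846 in every region, opposite in sign to Arntl. Among these, dorsal Dbp and ventral Ciart passed. A lower brain temperature stays open as well, as Cirbp, also induced by cold, changed by at least 0.129 but did not pass. Housing itself, which the design names, is a further candidate explanation that these libraries do not separate from the conditions at collection.

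Other libraries far from their group were 37.29 CPM of Npy in wildtype enriched and 62.29 in wildtype exercise housing of the dorsal dentate gyrus, 182.3 of Creb1 in CREB +/- exercise and 22.93 of Crem in labelled CREB -/- exercise housing of the visual cortex. Totals far from their group were 15.86 M counts in ventral CREB +/- enriched, 14.61 in ventral labelled CREB -/- control and 6.422 in cortical labelled CREB -/- exercise libraries. Chance gives about 1 in 20 groups, and 3 of 27 groups for Creb1, 1 of 27 for Crem, 2 of 9 for Npy, 0 of 9 for Penk and 3 of 27 for totals were found. The change between labelled CREB -/- and wildtype differed between the dorsal dentate gyrus and the visual cortex for 50 genes (Dcx, 0.58, edgeR adjusted p = 0.0104), between the ventral dentate gyrus and the visual cortex for 125 (Gpr83, 0.92, adjusted p = 1.25e-05, Acan, 0.95, adjusted p = 0.0147, and Crem, 0.36, adjusted p = 0.014), and between the dorsal and ventral dentate gyrus for 24 (Slc17a6, -2.32, adjusted p = 0.0318, and Shox2, -3.82, adjusted p = 0.00223). Slc17a6 belongs to thalamic and other projection neurons, so unlike tissue pieces cannot be told apart from a genotype effect in this last comparison. The enriched change differed between the dorsal dentate gyrus and the visual cortex for 2 genes, Npy (0.67, adjusted p = 0.0195) and Mylk3 (1.23, adjusted p = 0.0407). The interaction of genotype and housing in the dorsal dentate gyrus had 1 gene, Gm15564.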

How the results depend on the processing

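The fits with cell type lists as covariates, the fits without the libraries of high Ttr, Gm42418 or Cbln3, and every value for exercise against enriched housing were chosen after the data were seen. For each result below that moved, the cause was not tested. Regions stand in the order dorsal dentate gyrus, ventral dentate gyrus, visual cortex where not named, and counts are genes called by edgeR unless DESeq2 is named. Changed genes were missed in part on simulated counts (see the processing part), and depth was not varied there. Genes named in the text were followed, each counted once per region and comparison. Of 1598 values of 229 such called entries under other settings, 1443 stayed called in the same direction, 155 lost the call and 0 turned. Of 8010 values of 178 entries with 1 library left out, 7279 stayed called, 731 lost the call and 0 turned. The naming rule favoured small p and, in part, the same sign in every stratum, so these shares do not describe called genes at large. RLE scaling moved no count of called genes by more than 1.5 times. Of 392 list tests, which cover the 4 averaged comparisons set beforehand in each region and the 2 region comparisons but not exercise against enriched housing, 123 were called with the preset correlation and 2 with an estimated correlation, which uses the correlation between the genes of each list. With the preset correlation, 123 of these 123 stayed called under RLE scaling, 115 with no filter, 119 with unstranded counts, 92 with no run term, 110 with the replicate block and run term and 109 without the libraries of high Ttr, Gm42418 or Cbln3, and 0 turned.

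DESeq2 called 565 genes for enriched housing in the dorsal dentate gyrus (261 by edgeR), 23 in the ventral dentate gyrus (0 by edgeR, 2405 at unadjusted p under 0.05) and 12 in the visual cortex (2). It called 174, 14 and 386 for exercise against enriched housing (72, 5 and 125), 2 for exercise in the dorsal dentate gyrus (0) and 2 in the visual cortex (1), and 7 for ventral CREB +/- against wildtype (3). Within genotypes it called 2 for dorsal enriched housing in wildtype (0), 234 in labelled CREB -/- (0), 3 and 1 for ventral and cortical enriched housing in CREB +/- (0), and 0 and 21 for dorsal and ventral exercise in CREB +/- (1 and 0). For the interaction it called 5 in the dorsal and 3 in the ventral dentate gyrus (1 and 0).

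With no filter on low counts, dorsal against ventral dentate gyrus had 911 (544), ventral labelled CREB -/- against wildtype 723 (1133), dorsal CREB +/- against wildtype 12 (6), dorsal exercise against enriched housing 113 (72), dorsal exercise 2 (0) and ventral enriched housing 1 (0). Within genotypes and for the interaction it gave 3 for dorsal enriched housing in CREB +/- (0), 99 in labelled CREB -/- (0), 2 for dorsal exercise in CREB +/- (1), 4 for the dorsal and 2 for the cortical interaction (1 and 0), and 2 and 1 for cortical exercise in wildtype and labelled CREB -/- (0). With unstranded counts, dorsal CREB +/- against wildtype had 2, dorsal exercise 2, dorsal exercise in CREB +/- 0, the dorsal interaction 0 and ventral enriched housing 1. With no run term, labelled CREB -/- against wildtype had 1533 in the dorsal dentate gyrus and 1868 in the visual cortex (677 and 820), CREB +/- against wildtype 3 and 1 in the dorsal and ventral dentate gyrus, enriched housing 75 in the dorsal dentate gyrus and 1 in the visual cortex, and exercise against enriched housing 38 and 25 in these. It gave 0 for dorsal exercise in CREB +/-, 1 for dorsal enriched housing in labelled CREB -/- and 9 for ventral exercise in CREB +/-.

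Leaving out the libraries of high Ttr, Gm42418 or Cbln3 gave 3028 for ventral labelled CREB -/- against wildtype (1133), 2 and 1 for dorsal and ventral CREB +/- against wildtype, 1 and 0 for ventral and cortical enriched housing, 2 for ventral exercise, and 1 and 58 for ventral and cortical exercise against enriched housing. Within genotypes it gave 2 and 1 for dorsal and ventral enriched housing in CREB +/-, 16 for dorsal enriched housing in labelled CREB -/-, 0 for dorsal exercise in CREB +/- and 0 for the dorsal interaction. With cell type lists as covariates, labelled CREB -/- against wildtype had 254, 1869 and 399, CREB +/- against wildtype 2 and 1 in the dorsal and ventral dentate gyrus, enriched housing 14, 21 and 644, exercise 3 in the visual cortex, and exercise against enriched housing 46, 45 and 304.

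The labels do not say that a number marks an animal, though libraries of the same group and number share a run and a lane. The region comparisons treated them as separate libraries, and with group and number as a block gave 526 for dorsal against ventral and 2273 for dentate gyrus against visual cortex. The p-values of single genes in these comparisons are from the fit without this block, which counts such libraries as independent. The tests of whether a change differed between regions had this block, and were not run without it. Within regions, libraries of the same number correlated by 0.0318, 0.00797 and -0.0226 on average. Between regions the same group and number correlated by 0.269, 0.238 and 0.275 on average, and other numbers by -0.0662, -0.0582 and -0.0667. Of 45, 28 matched their own number best in each pair of regions, and 37, 33 and 36 correlations were over 0.1. Neither the 28 nor the mean for other numbers was set against the value that chance would give. They therefore cannot decide whether a number marks an animal, and 28 of 45 does not speak against it. The replicate block within a region joins libraries of the same number across groups, so it does not account for animals. With the replicate block and the run term, labelled CREB -/- against wildtype had 475 in the ventral dentate gyrus and 543 in the visual cortex, CREB +/- against wildtype 1, 1 and 4, enriched housing 604 in the dorsal dentate gyrus and 0 in the visual cortex, exercise 0 in the visual cortex, and exercise against enriched housing 158, 0 and 28. The block gave 40 for dorsal enriched housing in labelled CREB -/- and 7 for the dorsal interaction.

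Leaving out 1 library at a time, labelled CREB -/- against wildtype ranged from 516 to 1158, 424 to 1914 and 410 to 1250, CREB +/- against wildtype from 2 to 10, 1 to 6 and 1 to 4, enriched housing from 40 to 546, 0 to 164 and 1 to 7, and exercise against enriched housing from 28 to 318, 2 to 10 and 29 to 319. Dorsal exercise ranged from 0 to 2. In the dorsal dentate gyrus, enriched housing ranged from 0 to 2 in CREB +/- and 0 to 150 in labelled CREB -/- (150 without its enriched replicate 3), exercise in CREB +/- from 0 to 2, and the interaction from 0 to 2. In the ventral dentate gyrus, enriched housing in CREB +/- ranged from 0 to 1 (without CREB +/- control replicate 5) and exercise in CREB +/- from 0 to 3 (without wildtype exercise replicate 5). In the visual cortex, exercise in wildtype ranged from 0 to 2 (without wildtype exercise replicate 1, 2 or 4) and enriched housing in CREB +/- from 0 to 1.

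The libraries whose removal moved a count by over 1.5 times stand in the report for the larger counts and here for the others. Dorsal exercise had 1 to 2 without CREB +/- control replicate 1 or 6, labelled CREB -/- control replicate 4 or 5, labelled CREB -/- exercise replicate 1, or wildtype control replicate 3, enriched replicate 3 or exercise replicate 2. Dorsal enriched housing in CREB +/- had 1 to 2 without CREB +/- control replicate 1, 3, 4, 5 or 6, enriched replicate 2, 3, 4 or 6 or exercise replicate 4, labelled CREB -/- exercise replicate 3, or wildtype exercise replicate 1, 2 or 5. The same contrast in labelled CREB -/- had 1 to 150 without CREB +/- control replicate 4 or enriched replicate 2, 3, 5 or 21, labelled CREB -/- control replicate 3, 4 or 5, enriched replicate 2 or 3 or exercise replicate 3 or 4, or wildtype control replicate 1 or 3, enriched replicate 3 or exercise replicate 2 or 5. Dorsal exercise in CREB +/- had 0 without CREB +/- control replicate 5 or 6 or exercise replicate 1, 3 or 11 or wildtype enriched replicate 2, 3, 4 or 31, and 2 without labelled CREB -/- exercise replicate 4. The dorsal interaction had 0 without CREB +/- control replicate 5 or 6 or wildtype enriched replicate 4, and 2 without CREB +/- control replicate 1, 3 or 4 or exercise replicate 11 or wildtype enriched replicate 2 or exercise replicate 1 or 5. Ventral CREB +/- against wildtype had 1 without CREB +/- control replicate 2, 3, 4 or 6 or exercise replicate 3 or 4, labelled CREB -/- exercise replicate 3 or 4, or wildtype control replicate 4, enriched replicate 4 or exercise replicate 2 or 5, and 5 to 6 without CREB +/- control replicate 5 or wildtype enriched replicate 1. Ventral enriched housing had 1 to 164 without CREB +/- control replicate 3, enriched replicate 3 or 6 or exercise replicate 5, labelled CREB -/- control replicate 2 (164), enriched replicate 1, 2, 4 or 5 or exercise replicate 3, or wildtype enriched replicate 1. Ventral exercise against enriched housing had 2 to 3 without CREB +/- enriched replicate 2, 4, 5 or 21 or exercise replicate 1, 3 or 11, labelled CREB -/- enriched replicate 1 or exercise replicate 2, 3 or 5, or wildtype enriched replicate 3, 4 or 31 or exercise replicate 1 or 5, and 8 to 10 without CREB +/- enriched replicate 3 or wildtype exercise replicate 4. Cortical CREB +/- against wildtype had 1 without CREB +/- exercise replicate 4 or wildtype enriched replicate 4, and 4 without CREB +/- control replicate 5. Cortical enriched housing had 1 without CREB +/- enriched replicate 4, labelled CREB -/- control replicate 1 or 3 or enriched replicate 5, or wildtype control replicate 1 or 2 or enriched replicate 1, and 4 to 7 without CREB +/- control replicate 6 or enriched replicate 2, labelled CREB -/- enriched replicate 2 or wildtype enriched replicate 3 or 31. In CREB +/- it had 1 without CREB +/- control replicate 3 or 5, enriched replicate 3 or exercise replicate 5 or wildtype control replicate 1.

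Genes that turned sign were not called. Atf1 in labelled CREB -/- against wildtype had -0.0097 with the block in the dorsal dentate gyrus (-0.0355 to 0.0629 leaving out 1 library), and -0.0317 with no run term, -0.0256 with the block and -0.0062 without the libraries of high Gm42418 or Cbln3 in the visual cortex (-0.0096 to 0.0636). Atf1 in cortical CREB +/- against wildtype had -0.0118 with no run term and -0.0492 with the block (-0.0246 to 0.0431). Cortical Acan in labelled CREB -/- against wildtype was 0.24 ± 0.17 (edgeR adjusted p = 0.426) and had -0.12 with no run term. For exercise, dorsal Bdnf had 0.0086 without the libraries of high Gm42418 (-0.0558 to 0.0280 leaving out 1 library) and ventral Bdnf 0.0039 with unstranded counts and 0.0831 without those of high Ttr or Gm42418 (-0.0305 to 0.0373). Mki67 had -0.108 with unstranded counts in the dorsal dentate gyrus (-0.0030 to 0.0717), -0.116 with unstranded counts and -0.0055 with the block in the ventral dentate gyrus (-0.0882 to 0.107), and -0.0533 with the block in the visual cortex (-0.0403 to 0.142).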

Other observations

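The comparisons of exercise with enriched housing and the Lcn2 and pairing values below were chosen after the data were seen. Lcn2 was above 1 CPM in 6 of 16 enriched libraries of the dorsal dentate gyrus, 5 of 16 of the ventral dentate gyrus and 4 of 16 of the visual cortex, and in 0 of 15 control and 0 of 14 exercise libraries of any region. These regional counts share library numbers and are not independent of each other. No pair of libraries compared as duplicates was alike beyond counting noise, the lowest ratio of chi-square to its degrees of freedom being 3.22, 3.45 and 3.03 over 92 pairs in each region.

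Groups were redrawn 100 times per region and factor, the real grouping included, to count how often as many genes were called. Chance can be excluded (1 of 100) for labelled CREB -/- against wildtype, with 677 genes against at most 89 otherwise in the dorsal dentate gyrus, 1133 against 387 in the ventral dentate gyrus and 820 against 102 in the visual cortex. It can be excluded for enriched housing in the dorsal dentate gyrus with 261 against 3 (1 of 100). CREB +/- against wildtype had 6 against 5 (1 of 100), 3 against 0 (1 of 100) and 2 against 247 (3 of 100). Without the libraries of high Ttr or Gm42418 the dorsal and ventral counts fell to 2 and 1. The cortical count fell to 1 without CREB +/- exercise replicate 4 or wildtype enriched replicate 4, so chance is left open for all 3 counts. Exercise against enriched housing, chosen after the data were seen, had 72 against 189 (2 of 100) in the dorsal dentate gyrus. Another grouping called more genes there, so chance is left open. In the visual cortex it had 125 against 29 (1 of 100), which argues against chance but does not exclude it for a contrast chosen this way. The ventral count of this contrast, 5 against 130 (4 of 100), fell to 1 without the libraries of high Ttr or Gm42418. Exercise in CREB +/- of the dorsal dentate gyrus had 1 against 1 (4 of 100), a single gene lost under several other settings. Chance is left open for both, and these shares were not adjusted for the number of contrasts. It cannot be excluded for enriched housing in the visual cortex (2 against 852, 5 of 100), exercise in the visual cortex (1 against 3, 5 of 100) or the dorsal interaction (1 against 2, 9 of 100). The contrasts with 0 genes by edgeR, whose unadjusted counts stand in the report, cannot be judged this way, since any grouping gives at least 0 (100 of 100). Their highest other counts were 952 for enriched housing in the ventral dentate gyrus, 60 and 47 for exercise in the dorsal and ventral dentate gyrus, and 241 and 3 for the interaction in the ventral dentate gyrus and visual cortex. Within genotypes they were, for enriched and exercise housing in that order, 3 and 4 in wildtype, 345 in CREB +/- (enriched) and 19 and 1 in labelled CREB -/- in the dorsal dentate gyrus, 0 and 1, 30 and 4, and 3087 and 2180 in the ventral dentate gyrus, and 299 and 19, 2 and 892, and 4 and 3 in the visual cortex. Groupings that call several times the real count, up to 3087 genes, could point to a structure of the samples other than the labels, but what these groupings share was not tested. Among 21 groupings for the regions, the real one alone (1 of 21) gave 544 genes between dorsal and ventral dentate gyrus, against at most 15, and 2278 between dentate gyrus and visual cortex, against at most 24, so chance can be excluded.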
